A study of Mus musculus with 9 samples.

How the data were processed

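RNA sequencing libraries of splenic mouse CD4+ T cells, 3 naive, 3 activated at 37 °C and 3 activated at 39 °C, were analysed from 1 table per library. Each table holds raw counts of reads per gene as deposited, not normalised. The submitters' processing notes name FastQC, HISAT2, HTSeq, DESeq2 and the build GRCm38 without versions or roles, and the aligner and counter that made the tables, the annotation release and the strand setting are not stated. Per the labels, total RNA was isolated with TRIzol and prepared with a TruSeq RNA kit. Of 55573 gene identifiers 55480 matched the GENCODE M21 annotation, which supplied symbols and GRCm38 coordinates. The totals were 12647692 to 17605549 counts per library. Bounds against groups without counts used a floor of 3 counts over the group and cover counting error only, since reads without molecular identifiers are not independent molecules.

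Groups were taken from the labels, and the main choices, gene lists and naming rule were fixed before the data were examined. Genes were kept by filterByExpr (minimum count 10, minimum total 15), normalised by TMM and fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests with 1 fit of all 9 libraries. The tests are 2-sided and were adjusted by Benjamini-Hochberg over the 13328 genes, with 0.05 as the threshold. Standard errors were derived from the fold change and its F statistic. A total of 29 gene lists, 8 of them markers of cell types that a spleen preparation could hold, were tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 27 lists with enough members, and again with an estimated correlation and with fry. The genes named are, for 39 °C against 37 °C and for 37 °C against naive, the 6 with the largest rise and the 6 with the largest fall among called genes with a mean of at least 5 CPM and no overlap of single samples, passing over predicted gene models, up to 3 called members of each list by adjusted p, and 24 genes fixed by name. For 39 °C against naive the same genes were used.

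The activation contrasts share the naive libraries, so 9 libraries without any group difference were simulated 20 times around the naive means. The simulated naive libraries were shared by both contrasts. Genes were drawn independently, so spread that real libraries share across genes is left out. Simulated counts with known changes were used to check the fit. At a 4-fold change 49 of 50 genes were recovered, at 2-fold 35 of 50, at 1.5-fold 29 of 50 and at the smallest simulated change, 0.32 on the log2 scale, 3 of 48, among 13141 genes, with 6 unchanged genes called and 0 calls in the wrong direction. Alternatives were RLE, upper-quartile or library size scaling, other count filters, a stricter threshold, a 2-fold minimum, a replicate block, removal of abundant genes, the 6 libraries of a contrast alone, DESeq2 1.42.0 and leaving out each library. A correction for gene length and GC content and a covariate of the ribosomal protein share were added after the data were examined. So was a test of depth by keeping 50% of the reads, or a share of 0.25, at random. The outlier check needs at least 4 samples per group and was not applied.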

Results

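RNA was sequenced from CD4+ T cells of the spleen of B6 mice, in 3 groups of 3 libraries each. The naive cells were not activated. The labels name CD4+ T cells as the source but spleen cells as what was put into culture, and do not say whether CD4+ cells were isolated before or after the activation, so the activation contrasts can include the removal of other cells. The other groups were activated for 3 hours on plates coated with antibodies against CD3 and CD28. These antibodies engage the T cell receptor and a costimulatory receptor. The incubator was at 37 °C or at 39 °C, a febrile temperature. The total count per library ranged from 12647692 to 17605549, with means of 15375196 ± 2026313 in the naive group, 13903903 ± 793964 at 37 °C and 14427011 ± 1810748 at 39 °C (SD, n = 3). Of 29586 genes with any count, 13328 had enough counts to be tested. The labels do not say whether the libraries of a group came from separate mice or cultures, so the spread between libraries may be technical and the p-values measure only the spread between these samples. Beside log2 fold changes, ± gives the standard error of the edgeR fit, with n = 3 per group throughout, and beside CPM (counts scaled to a common library size) it gives the SD.

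The comparison of cells activated at 37 °C with naive cells asks what 3 hours of stimulation changed. Genes of early T cell activation rose together. Il2, which encodes the T cell growth factor interleukin 2, rose from 0.357 ± 0.165 to 32.1 ± 2.05 CPM (log2 fold change 6.51 ± 0.19), and Il2ra, its high-affinity receptor chain, rose by a log2 fold change of 2.97 ± 0.063. The costimulatory ligand gene Tnfsf14 (6.39 ± 0.17), the semaphorin gene Sema7a (6.30 ± 0.15), the growth factor gene Pdgfb (7.04 ± 0.14) and the glycine transporter gene Slc6a9 (6.66 ± 0.31) were among the 6 genes with the largest rise under the naming rule, which asks for a mean of at least 5 CPM over all libraries and passes over predicted gene models. Chac1, a glutathione-degrading enzyme of the stress response, had no count in any naive library and was at least 194-fold higher at 37 °C, against a floor of 3 counts over the naive group. The genes with the largest fall under this rule were the haemoglobin genes Hbb-bs and Hba-a1, the carrier gene Slc16a5 (-5.42 ± 0.14), the insulin-like growth factor binding protein gene Igfbp4 (-4.94 ± 0.095), the AMP deaminase gene Ampd1 (-4.73 ± 0.26) and the Notch target Dtx1 (-4.35 ± 0.10), which went from 310 ± 28.4 to 15.2 ± 1.81 CPM. In all, 4114 genes were higher and 4240 lower than in naive cells, 62.7% of those tested, and 1435 and 1398 of these differed by at least 2-fold. Il2 (ENSMUSG00000027720) lies on chromosome 3 at 37120523 to 37125959 and Dtx1 (ENSMUSG00000029603) on chromosome 5 at 120680202 to 120711927, in GRCm38. The labels do not say whether naive cells spent the same 3 hours in medium, so culture and activation are not separated in this contrast.

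Of 29 measured genes of T cell activation and cytokines, 27 rose and 1 fell at 37 °C (adjusted p = 7.96e-59 and adjusted p = 0.000859 with an estimated correlation). Irf4, a transcription factor induced by T cell receptor signals, rose by 4.85 ± 0.096, and the amino acid transporter gene Slc7a5 by 3.46 ± 0.072, both on the log2 scale. Ribosome biogenesis factors rose in 31 of 32 measured members (adjusted p = 6.3e-29 and adjusted p = 0.00114 with an estimated correlation), among them Nolc1 (2.20 ± 0.08), Polr1b (2.21 ± 0.078) and Grwd1 (2.21 ± 0.066). Heat shock chaperones, which assist protein folding, rose in 25 of 27 (adjusted p = 4.23e-26 and adjusted p = 0.0178 with an estimated correlation), with Hsph1 at 4.02 ± 0.079, Hspa4l at 3.14 ± 0.085 and Hsp90aa1 at 2.34 ± 0.071. NF-kB targets rose in 19 of 22 and fell in 1 (adjusted p = 3.63e-21 and adjusted p = 0.00114 with an estimated correlation), with the subunit gene Nfkb1 at 2.43 ± 0.081 and the regulator gene Nfkbid at 2.82 ± 0.074. Immediate early genes rose in 18 of 26 and fell in 8 (adjusted p = 1.18e-13 and adjusted p = 0.0178 with an estimated correlation). Egr2 (4.20 ± 0.076), Egr3 (3.81 ± 0.075) and Nr4a2 (3.56 ± 0.07) rose, whereas Junb, an AP-1 subunit gene, fell by a log2 fold change of -1.84 ± 0.086. Regulatory T cell genes rose in 11 of 16 and fell in 3 (adjusted p = 0.000211 and adjusted p = 0.0222 with an estimated correlation), including Foxp3, the lineage factor, at 0.93 ± 0.076 and Tgfb1 at 1.34 ± 0.073.

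**Figure D1:**
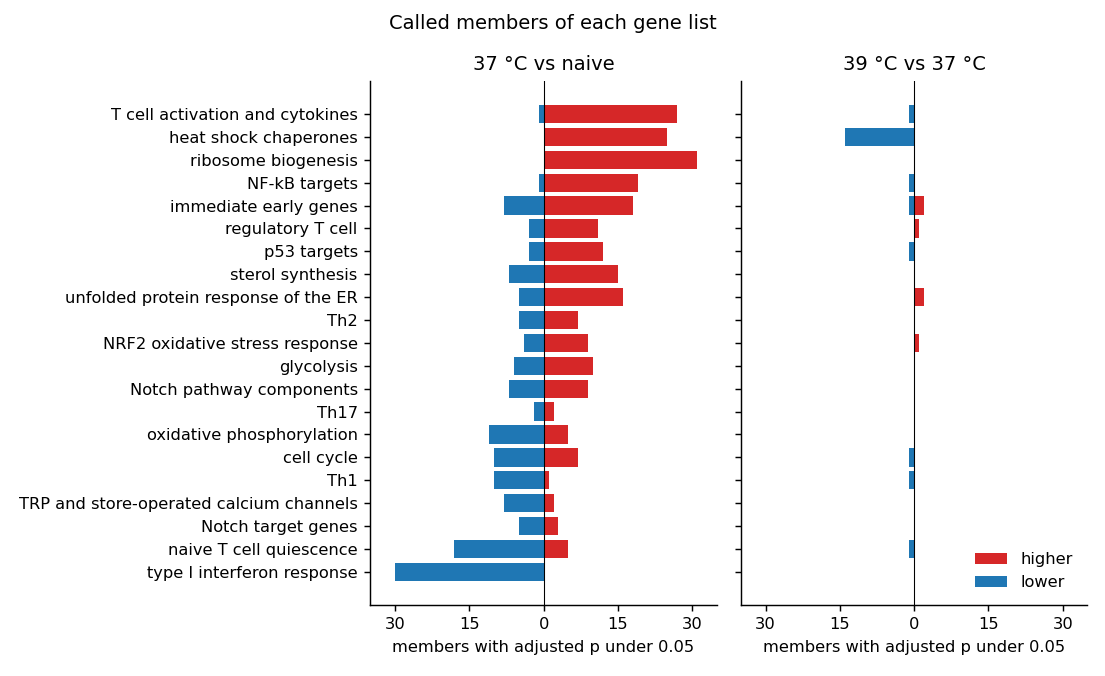
Number of members called higher (red, to the right) or lower (blue, to the left) in each fixed gene list, for activation at 37 °C against naive cells (left panel) and for 39 °C against 37 °C (right panel), with adjusted p under 0.05 as the threshold and 3 libraries per group. The chaperone list has 25 members higher in the left panel and 14 lower in the right panel.

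Type I interferon response genes, which encode antiviral proteins, fell in 30 of 32 measured members at 37 °C (adjusted p = 2.03e-23 and adjusted p = 0.000859 with an estimated correlation), for example Oas2 (-2.89 ± 0.10), Ifit3 (-2.71 ± 0.10) and Zbp1 (-2.14 ± 0.079). Markers of other spleen cells were also lower in the activated libraries. The summed level of 18 B cell markers was 1531 ± 154 CPM in naive, 607 ± 18.3 at 37 °C and 626 ± 24.2 at 39 °C. At 37 °C, 16 of these markers fell and 1 rose (adjusted p = 1.45e-06 and adjusted p = 0.118 with an estimated correlation), with Cd22 at -2.98 ± 0.16 and the immunoglobulin heavy chain gene Ighm at -2.10 ± 0.08. Erythroid and platelet markers fell in 5 of 6 (adjusted p = 6.48e-07 and adjusted p = 0.0296 with an estimated correlation), and the sum over 14 of the 15 listed genes, those whose symbols were matched, was 183 ± 45.3 CPM in naive and 9.94 ± 0.511 at 37 °C. Hba-a1 (-5.90 ± 0.25), Hba-a2 (-6.54 ± 0.42) and Hbb-bs (-6.07 ± 0.27) share reads with near-identical copies, so their single values are uncertain. The 4 measured NK cell markers fell (adjusted p = 0.0329 and adjusted p = 0.172 with an estimated correlation), and both CD8 T cell markers fell without a call for the list (adjusted p = 0.121). Myeloid markers rose in 1 and fell in 6 of 10 (adjusted p = 0.13), though the list test passed when any 1 of the 37 °C libraries was left out, with adjusted p of 0.0332 to 0.0383. S100a9, the 1 measured neutrophil marker, was at least 16.3-fold lower at 37 °C, where it had no count. Stroma and endothelium markers were below the count filter of edgeR, while DESeq2 tested 4 and called 1 lower. Their sum of 29.1 CPM in naive library 2 stood apart from 1.10 and 0.846 in the other naive libraries. CD4 T cell markers, of which 4 rose and 7 fell among 16 (adjusted p = 0.736), summed to 9521 ± 1130 CPM in naive and 9362 ± 256 at 37 °C. Ribosomal protein genes took 12.5 ± 2.20% of counts in naive libraries, 8.58 ± 0.551% at 37 °C and 9.36 ± 0.886% at 39 °C.

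The series title names TRPV channels, Notch and T cell differentiation, and these genes were followed whatever their values. At 37 °C, 9 of 24 measured Notch pathway components rose and 7 fell (adjusted p = 0.991). Rbpj, the DNA-binding partner of Notch, rose by 1.18 ± 0.074 and Notch2 by 0.64 ± 0.15, while Notch1 stood at 0.55 ± 0.25 (adjusted p = 0.0781, edgeR), and at 0.80 with a call without naive library 2. It was also called with a replicate block (0.63), with any count (0.54) and with the length and GC trend removed (0.51), and not by DESeq2. Naive libraries 1, 2 and 3 had 84.3, 214 and 186 CPM of Notch1, and the 37 °C libraries 239, 258 and 212 CPM. The higher Notch1 value at 37 °C thus rests mostly on naive library 1, as naive library 2 lay within the 37 °C range. With the ribosomal protein share as a covariate, an alternative added after the data were examined, Notch2 was at -0.019 and Notch1 at -0.55. That share did not overlap between naive and 37 °C libraries, so this covariate is confounded with activation. The ligand gene Jag2 (-1.53 ± 0.15) and the secretase gene Psen2 (-1.25 ± 0.068) fell. Among 9 measured Notch targets 3 rose and 5 fell (adjusted p = 0.294). Their median was -0.62 and their mean 0.20, so that median and test differ in sign. Cdkn1a (5.57 ± 0.11) and Il2ra (2.97 ± 0.063), which raise the mean, stand in other lists too. Dtx1 fell (-4.35 ± 0.10). Hes1 and Nrarp, below the count filter, had 21 and 30 counts over the naive group and 4 and 8 over the 37 °C group. TRP and store-operated calcium channel genes rose in 2 and fell in 8 of 13 (adjusted p = 0.285), with Orai1, the pore of store-operated entry, at 1.99 ± 0.12 and Trpv2 at -1.13 ± 0.078. Trpv4 was called lower at -0.65 ± 0.25 (adjusted p = 0.0407), a call lost without 37 °C library 2 or 3, any 39 °C library or naive library 1, with values of -0.70 to -0.48. It was also lost by DESeq2, with any count, a replicate block, the 6 libraries alone or the length and GC trend removed (-0.66 to -0.63), and with the ribosomal protein share as covariate (-0.22). Trpv1 had 0 counts in naive and 37 °C libraries and 2 counts over the 39 °C group, so no fold is given. Of the Th1 genes 1 rose and 10 fell among 14 (adjusted p = 0.152), with the lineage factor Tbx21 at 2.78 ± 0.22. Th17 genes rose in 2 and fell in 2 of 10 (adjusted p = 0.121). Th2 genes rose in 7 and fell in 5 of 15 (adjusted p = 0.0464 and adjusted p = 0.118 with an estimated correlation), with Gata3 at -0.76 ± 0.087. The Th2 list call was lost without naive library 1 or 2 (adjusted p = 0.103 and 0.0864). It was also lost with library size scaling, a replicate block, the length and GC trend removed or the ribosomal protein share (adjusted p of 0.0721 to 0.396).

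The remaining lists covered metabolism, stress and proliferation. Naive T cell quiescence genes rose in 5 and fell in 18 of 24 (adjusted p = 1.45e-06 and adjusted p = 0.184 with an estimated correlation), with Tsc22d3 at -1.68 ± 0.096 and Pik3ip1 at -1.29 ± 0.071. Sterol synthesis genes rose in 15 and fell in 7 of 23 (adjusted p = 0.0174 and adjusted p = 0.0808 with an estimated correlation). Glycolysis genes rose in 10 and fell in 6 of 19 (adjusted p = 0.0355 and adjusted p = 0.172 with an estimated correlation), with hexokinase Hk2 at 3.72 ± 0.20, and the list call was lost without naive library 2 (adjusted p = 0.0663). Genes of the unfolded protein response rose in 16 and fell in 5 of 24 (adjusted p = 0.000211 and adjusted p = 0.118 with an estimated correlation). The p53 target list rose in 12 and fell in 3 of 17 (adjusted p = 1.13e-05 and adjusted p = 0.0887 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 5.57 ± 0.11 and Sesn2 at 3.23 ± 0.09. The list test passed no threshold for NRF2 response genes, of which 9 rose and 4 fell among 16 (adjusted p = 0.294), cell cycle genes, of which 7 rose and 10 fell among 24 (adjusted p = 0.881), and oxidative phosphorylation genes, of which 5 rose and 11 fell among 35 (adjusted p = 0.428). The NK cell list call was lost without naive library 1 (adjusted p = 0.0551), with the length and GC trend removed (adjusted p = 0.0832) and with the ribosomal protein share (adjusted p = 0.107). Under that covariate the NRF2 list passed. Adjusted over the list alone, the counts at 37 °C were those over all genes in each list except TRP and calcium channels, with 9 lower, and myeloid markers, with 7 lower. Of the 27 lists tested, 16 passed at the preset correlation and 8 with an estimated correlation.

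The comparison of 39 °C with 37 °C asks what the febrile temperature changed in cells activated for the same time. Heat shock chaperone genes were lower at 39 °C. Hsph1, a co-chaperone of the Hsp70 system, was at 922 ± 20.1 CPM at 37 °C and 453 ± 10.0 CPM at 39 °C, against 57.0 ± 3.87 CPM in naive cells (log2 fold change -1.03 ± 0.07, adjusted p = 2.83e-05, edgeR). Of 27 measured chaperone genes 14 fell and 13 were not called, and 21 fell when adjusted over the list alone. The median log2 fold change was -0.40 and the list test gave adjusted p = 1.07e-61 (adjusted p = 0.0101 with an estimated correlation). The Hsp90 gene Hsp90aa1 fell by 0.64 ± 0.067 on the log2 scale and its co-chaperone gene Ahsa2 fell by 0.87 ± 0.077. The constitutive Hsp70 gene Hspa8 was at -0.47 ± 0.085 (adjusted p = 0.0254), a call lost when any 1 of the 6 activated libraries was left out, with values of -0.50 to -0.44. The heat-inducible pair Hspa1b (-0.60 ± 0.12, adjusted p = 0.0456) and Hspa1a (-0.33 ± 0.18, adjusted p = 0.716) share reads, so both values are uncertain. The call of Hspa1b was lost when any 1 activated library or naive library 3 was left out, with values of -0.70 to -0.52. Dnajb1, an Hsp40 gene, was not called at -0.30 ± 0.08, but was called without naive library 1 or 2, at -0.30 in both. It was also called with the 6 libraries alone (-0.30), the length and GC trend removed (-0.32) or the ribosomal protein share (-0.36). The mean log2 CPM of the 27 chaperones was 5.93 ± 0.0845 in naive cells, 7.49 ± 0.0116 at 37 °C and 7.01 ± 0.0375 at 39 °C. The 2-sided exact permutation test of the difference of -0.47 gave p = 0.1, the smallest that 3 against 3 samples allow. Of the 18 B cell markers edgeR called 0 between the temperatures, with 8 at unadjusted p under 0.05, and DESeq2 called 1.

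**Figure D2:**
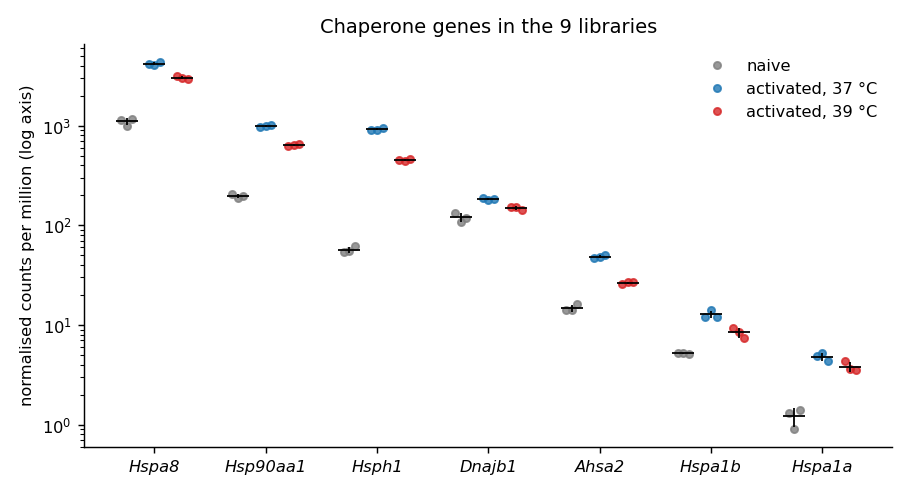
Normalised counts (CPM) of 7 chaperone genes on a log axis in the 9 libraries, with 1 point per library, a horizontal line at the mean of each group and a vertical bar for the SD (n = 3). Hsph1 had means of 57.0 in naive cells, 922 at 37 °C and 453 at 39 °C, while Hspa1a and Dnajb1 were not called between the temperatures.

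Outside the chaperones, the protease inhibitor gene Serpine2 (ENSMUSG00000026249, chromosome 1, 79794197 to 79861180, GRCm38) had the largest fall under the naming rule with its 5 CPM limit, from 17.0 ± 0.944 to 2.55 ± 0.359 CPM (log2 fold change -2.74 ± 0.17, adjusted p = 1.1e-05). Gprasp1, which sorts G protein-coupled receptors, fell from 220 ± 4.99 to 93.0 ± 5.23 CPM (-1.24 ± 0.073). The planar polarity gene Prickle1 (-1.21 ± 0.18), Vwce (-1.26 ± 0.14) and the lectin gene Lman2l (-1.17 ± 0.093) also fell, as did the class I histocompatibility gene H2-Q10 (-1.62 ± 0.16), whose reads are shared with near-identical genes and whose value is uncertain. The genes with the largest rise under this rule were Gtse1 (ENSMUSG00000022385, chromosome 15, 85859745 to 85876573), a gene of the S and G2 phases, at 1.36 ± 0.15 (adjusted p = 0.00101), the stress factor gene Ddit3 at 0.59 ± 0.084, the pseudokinase gene Trib3 at 0.48 ± 0.082, the neutral amino acid transporter gene Slc1a4 at 0.53 ± 0.088, the mitochondrial phosphoenolpyruvate carboxykinase gene Pck2 at 0.51 ± 0.071 and the reductase gene Cyb5r1 at 0.49 ± 0.066. Calls were lost when 1 library was left out for Prickle1 (37 °C library 1, 39 °C library 2 or 3, values of -1.13 to -1.10), Trib3 (any 37 °C library, 39 °C library 1 or 2, 0.42 to 0.51) and Slc1a4 (any activated library, 0.50 to 0.55). In all, 18 genes were higher and 83 lower at 39 °C, 0.758% of those tested, while 1061 had an unadjusted p under 0.05. At least 2-fold differences were 4 higher and 25 lower. The samples of the 2 temperatures did not overlap in any of the 101 called genes, against 20.9% of all genes and 10% by chance. For called genes this largely follows from the call itself, so it is no separate support. Lbp (-4.20 ± 0.35) and Soat2 (4.05 ± 0.36), both below the expression limit of the naming rule and named after their values were seen, had the most extreme called fold changes. Higher and lower counts were 7 and 36, 8 and 43, and 7 and 38 without 37 °C library 1, 2 or 3, and 8 and 43, 7 and 30, and 8 and 37 without 39 °C library 1, 2 or 3. They were 89 and 202 without naive library 1 and 30 and 122 without naive library 2, which enter this contrast only through filtering, normalisation and the shared estimate of the spread.

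**Figure D3:**
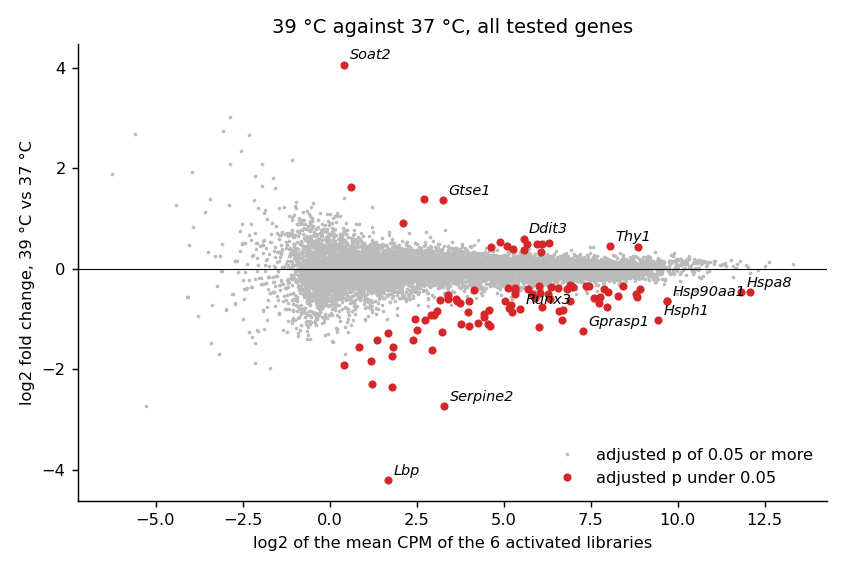
Log2 fold change of 39 °C against 37 °C (vertical) against the log2 of the mean CPM of the 6 activated libraries (horizontal), with 1 point per tested gene and called genes in red. Of the 101 called genes 83 lie below 0 and 18 above, with Hsph1 at -1.03 and Gtse1 at 1.36.

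Notch and TRP genes were not called between the temperatures. By edgeR 0 of 24 Notch pathway components passed (1 at unadjusted p under 0.05, 0 by DESeq2), with Notch1 at -0.17 ± 0.25, Notch2 at -0.12 ± 0.15 and Rbpj at 0.079 ± 0.071. The median of this list was -0.015, its mean -0.023, and the test pointed up (adjusted p = 0.975), so their signs differ. Of 9 measured Notch targets 0 passed (3 at unadjusted p under 0.05, 0 by DESeq2), 1 higher and 1 lower when adjusted over the list alone (adjusted p = 0.767), with Dtx1 at -0.36 ± 0.11. Hes1 and Nrarp were below the count filter, with 4 and 8 counts over the 37 °C group and 3 and 8 over the 39 °C group. Of 13 TRP and calcium channel genes 0 passed (2 at unadjusted p under 0.05, 0 by DESeq2; adjusted p = 0.822), with Trpv2 at 0.14 ± 0.08 and Trpv4, at 1.17 to 1.66 CPM, at 0.51 ± 0.26. Lineage genes of T helper cells were mostly not called either. In the Th1 list Runx3, a factor of Th1 and CD8 cells, fell by 0.81 ± 0.096 (adjusted p = 0.00134) and Tbx21 stood at -0.44 ± 0.18. Tbx21 was called only with the ribosomal protein share as covariate, at -0.59. In this list 2 members fell when adjusted over the list alone. The list of 14 Th1 genes fell (adjusted p = 0.0016, adjusted p = 0.0866 with an estimated correlation). Th2 genes (adjusted p = 0.423; Gata3 -0.063 ± 0.09, Il4 -0.49 ± 0.41) and Th17 genes (adjusted p = 0.641) had 0 members called by edgeR and 0 by DESeq2, with 0 and 1 at unadjusted p under 0.05. Ifng was below the count filter, with 16 and 19 counts over the groups. Among regulatory T cell genes Gpr83 rose by 0.46 ± 0.075, a call lost without 37 °C library 1 or 3 or any 39 °C library (0.41 to 0.47), and Foxp3 was at 0.076 ± 0.074, with adjusted p = 0.413 for the list and 1 higher adjusted over the list alone.

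Activation genes differed by temperature in single members. Il2 (0.20 ± 0.10), Il2ra (0.14 ± 0.057) and Cd69 (0.19 ± 0.088) were not called, and in the activation list edgeR called only Tnfsf14, lower at -0.50 ± 0.10. DESeq2 called 1 higher and 1 lower in this list, as did adjustment over the list alone, and the list test gave no call (adjusted p = 0.822). Immediate early genes Egr3 (0.44 ± 0.065) and Atf3 (0.38 ± 0.076) rose and Fosb (-0.83 ± 0.091) fell by edgeR. DESeq2 called 3 higher and 2 lower, with 4 higher and 4 lower adjusted over the list alone (adjusted p = 0.455). The NF-kB inhibitor gene Tnfaip3 (-0.50 ± 0.08), the death receptor gene Fas (-0.58 ± 0.082), the cyclin gene Ccnd2 (-0.64 ± 0.094) and the phosphatase gene Dusp10 (-0.35 ± 0.068) fell and the cystine transporter gene Slc7a11 (1.63 ± 0.30, at 0.743 to 2.32 CPM) rose, each the 1 member of its list that edgeR called. These lists were NF-kB targets (adjusted p = 0.767), p53 targets (adjusted p = 0.767), cell cycle (adjusted p = 0.975), quiescence (adjusted p = 0.767) and the NRF2 response (adjusted p = 0.423). Adjusted over the list alone, they had 2 higher and 2 lower, 1 and 1, 1 lower, 1 lower, and 1 higher. DESeq2 called 1 lower, 1 higher and 1 lower, 1 lower, 1 higher and 1 lower, and 1 higher. Ddit3 and Trib3 were the 2 called members of the unfolded protein response list (adjusted p = 0.0722, 3 higher and 1 lower adjusted over the list alone), whose test passed without 39 °C library 3 (adjusted p = 0.0429) and with library size scaling (adjusted p = 0.04). Leaving out any activated library or naive library 3 ended the calls of Tnfsf14 (-0.53 to -0.47), Atf3 (0.32 to 0.42), Dusp10 (-0.37 to -0.33) and Slc7a11 (1.45 to 1.86), and any activated library that of Tnfaip3 (-0.52 to -0.47). The call of Egr3 ended without any 37 °C library or 39 °C library 2 or 3 (0.40 to 0.46), that of Ccnd2 without 39 °C library 1 or 2 (-0.64 to -0.61), and that of Fas without 39 °C library 2 (-0.58).

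Lists with few or no called members could still shift as a whole. Sterol synthesis genes were higher at 39 °C, with 20 of 23 above 0 (adjusted p = 0.0201 and adjusted p = 0.134 with an estimated correlation), and so were oxidative phosphorylation genes, with 30 of 35 above 0 (adjusted p = 0.0221 and adjusted p = 0.928 with an estimated correlation). CD4 T cell markers were higher as a list (adjusted p = 0.0316 and adjusted p = 0.913 with an estimated correlation), with Thy1 the called member at 0.45 ± 0.076, a call lost when any 1 activated library was left out (0.41 to 0.48). The sterol call was lost without 37 °C library 2 (adjusted p = 0.096). The oxidative phosphorylation and CD4 marker calls were lost without 37 °C library 2 or 39 °C library 1 or 2, with adjusted p of 0.0529 to 0.428 and 0.0529 to 0.244. Both were also lost with the ribosomal protein share as covariate (adjusted p = 0.79 and adjusted p = 0.107), and the oxidative phosphorylation call with the length and GC trend removed (adjusted p = 0.188), alternatives added after the data were examined. The ribosomal protein share was 8.58 ± 0.551% of counts at 37 °C and 9.36 ± 0.886% at 39 °C. No call was made for glycolysis (adjusted p = 0.767), ribosome biogenesis (adjusted p = 0.462) or interferon response genes (adjusted p = 0.455). Among marker lists none was called for CD8 T cells (adjusted p = 0.975), B cells (adjusted p = 0.393), myeloid cells (adjusted p = 0.767), NK cells (adjusted p = 0.413) or erythroid cells and platelets (adjusted p = 0.767). The B cell list passed with the ribosomal protein share as covariate (adjusted p = 0.0159). Across the 15 tested lists with 0 members called by edgeR, 27 members had an unadjusted p under 0.05 and DESeq2 called 2. Adjusted over the list alone, 1 interferon gene was lower, and 1 B cell marker was higher and 3 were lower. Of 27 lists tested 5 passed at the preset correlation, 1 with an estimated correlation, and 2, 3 and 3 without 37 °C library 2 and 39 °C libraries 1 and 2.

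Cells activated at 39 °C were compared with naive cells through the genes already named. Il2 (6.71 ± 0.19), Il2ra (3.11 ± 0.063), Irf4 (4.80 ± 0.096) and Egr3 (4.25 ± 0.076) rose, and Dtx1 (-4.71 ± 0.11), Igfbp4 (-5.08 ± 0.096) and Oas2 (-2.99 ± 0.10) fell. Chac1 was at least 245-fold higher than in naive cells. Chaperones rose in 24 of 27 and fell in 2, or 25 and 2 adjusted over the list alone (adjusted p = 1.78e-15 and adjusted p = 0.0398 with an estimated correlation), with a median of 1.09 against 1.65 at 37 °C and Hsph1 at 2.99 ± 0.076. In all, 3887 genes were higher and 3968 lower, and 1245 and 1242 of these by at least 2-fold. Of 27 lists 16 passed, 10 higher and 6 lower, and 9 held with an estimated correlation. Median and test differed in sign for Notch targets (median -0.42), Th17 genes (-0.23) and CD4 T cell markers (-0.088), none of them called.

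The activation responses at the 2 temperatures were set side by side. Among the 13328 genes 3599 were higher and 3703 lower than naive at both temperatures, 7302 in the same direction, while 1049 were called only at 37 °C and 550 only at 39 °C. A call at 1 temperature alone does not show a difference, which is tested by the 101 genes above. Opposite calls were made for 3 genes, named after their values were seen. Parp3, a poly(ADP-ribose) polymerase gene, was at 0.60 ± 0.064 at 37 °C and -0.23 ± 0.065 at 39 °C, Lbp at 1.02 ± 0.24 and -3.18 ± 0.39, and the sterol acyltransferase gene Soat2, at most 2.54 CPM, at -1.71 ± 0.48 and 2.34 ± 0.28. Independent lists of these sizes would share 1200 higher and 1262 lower genes. Unchanged groups, with the naive libraries simulated as well, shared 0.05 genes on average over 20 simulations. Genes were drawn independently there, so the simulated values leave out spread that real libraries share across genes. Across genes, which are not independent replicates, the fold changes had r = 0.965 and a covariance of 0.963, against a simulated 0.488 and 0.0197. The 3 naive libraries are too few to split, so part of the excess of shared calls may come from the shared controls.

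**Figure D4:**
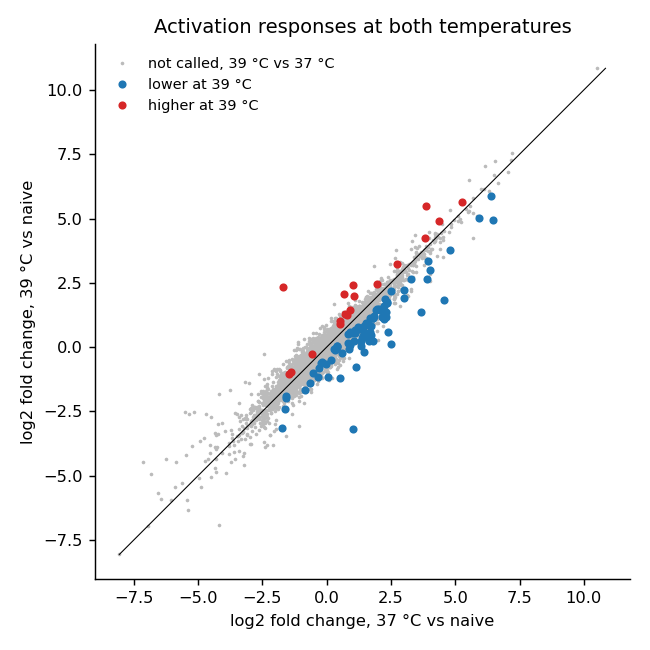
Log2 fold change of activated against naive cells at 39 °C (vertical) and at 37 °C (horizontal), with 1 point per tested gene, the line of equal change, and the genes called between the temperatures in blue (83 lower at 39 °C) and red (18 higher). The points follow the line with r = 0.965, and Soat2 is the red point above 0 at 39 °C and below 0 at 37 °C.

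Genes called between the temperatures, whether lower or higher at 39 °C, were mostly genes that rose on activation. Activation is taken here as the mean of both activated groups against naive, a contrast orthogonal to the temperature contrast. Of the 83 genes lower at 39 °C, 64 rose, 14 fell and 5 were not called. Hsph1, Serpine2, Gprasp1 and Hsp90aa1 were higher in both activated groups than in naive cells, whereas Runx3 was at -0.33 ± 0.092 at 37 °C and -1.14 ± 0.095 at 39 °C. Of the 18 genes higher at 39 °C, 14 rose and 3 fell on activation. Among the 13227 other genes 32.0% rose and 33.6% fell. These genes were not matched on counts, on which a call depends, so part of the difference in shares may come from expression. Across genes the temperature effect had r = -0.19 with the activation effect, against -0.034 to 0.063 in simulated unchanged groups. That range leaves out spread that real libraries share across genes, so it may be too narrow. The count of 64 was 29, 33 and 30 without 37 °C library 1, 2 or 3, 32, 25 and 29 without 39 °C library 1, 2 or 3, and 147 without naive library 1.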

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

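The tests on the share of B cells and on both forms of dilution were chosen after the result was seen, and the length and GC correction was added after the data were examined. The activation effect differed between 39 °C and 37 °C in 101 genes, by the edgeR test of that difference. Among them 3 genes, Lbp, Parp3 and Soat2, chosen after their values were seen, were called in opposite directions against naive cells. The difference of the activation effects of the heat shock chaperones had a median log2 value of -0.40. The 10 splits of 6 samples are too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes, with 101, 8354 and 7855 genes for 39 °C against 37 °C, 37 °C against naive and 39 °C against naive, and a highest other count of 0 by edgeR, where up to 525, 577 and 913 genes had an unadjusted p under 0.05.

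Chaperone genes lower at 39 °C were weighed against 3 technical explanations and the temperature itself. Weaker activation at 39 °C as the whole cause is argued against by the list median of -0.40, since the medians of 10000 random lists matched on expression and activation fold lay between -0.084 and 0.011 at the 5th and 95th percentiles and 0 of them were at or below it. After a length and GC trend was removed the median was -0.45, which argues against such a trend. An exchange of the 37 °C and 39 °C labels cannot be told apart from a response to temperature, because the cold-inducible genes Cirbp and Rbm3 had a mean log2 fold change of 0.11 ± 0.060 (SE), on the side of exchanged labels but within the 2 standard errors set beforehand. A biological response to 39 °C, the difference that the design names, stays open as well and may or may not be what the libraries show.

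Markers of other spleen cells were lower in activated than in naive libraries. A lower share of B cells alone would give their markers 1 common fold change if only B cells transcribed them. The log2 fold changes of the 18 measured B cell markers at 37 °C ranged from -2.98 to 1.34, with a heterogeneity Q of 1058 on 17 degrees of freedom. These values argue against 1 common fold change. They cannot argue against a lower share where other cells, such as the T cells, transcribe some of the markers, which was not tested. A lower share beside changes of expression stays open. Dilution of every other cell type alike is argued against only weakly, by 1 of 6 pairs of lists, B and NK cells, whose medians were 1.22 apart against a sum of standard errors of 1.02. Dilution of B and erythroid cells alike is argued against by a larger difference, with the erythroid median -4.82 relative to the B cell median and a sum of standard errors of 1.26. These standard errors are of the spread across 18 B cell, 4 NK cell and 6 erythroid and platelet genes, not across libraries. Marker genes are not independent replicates, and the 6 include haemoglobin genes that share reads. Both comparisons also assume that only the named cells transcribe the markers. Handling of the naive and activated cells, which the labels do not describe separately, stays open and was not tested.

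Within the groups 1 axis held 43.6% of the variance between libraries of a group, with naive library 1 at 33.2 and naive library 2 at -28.2. The scores had the same order as the share of counts from ribosomal protein genes in all 3 groups, for example 14.8%, 12.3% and 10.5% in naive libraries 1, 3 and 2. These genes are part of the axis, and their share is the covariate under which 181 genes were higher and 301 lower at 39 °C. Across genes the loadings had a Spearman rho of -0.39 with exon length and of -0.056 with GC content. A trend with gene length, and not with GC content, goes with this axis. The test cannot separate a length bias between libraries from differences in the expression of short genes. A varying share of B cells and myeloid cells also goes with the axis, though narrowly, with the median loading of B cell markers at percentile 98.2 of matched random lists. No biological explanation other than the share of these cells was tested for this axis, and neither test excludes the other explanation.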

How the results depend on the processing

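The length and GC correction, the ribosomal protein covariate and the test of depth were chosen after the data were examined. The heat shock chaperone list stayed lower at 39 °C with adjusted p of at most 0.0101 in each of 13 alternatives. Of 29 called named genes between the temperatures 14 kept their call in every alternative and 15 lost it in some, and of 96 called at 37 °C against naive 93 kept it. Under the RLE, 1 CPM and abundant-gene alternatives all 101 genes kept their call, and under DESeq2 100 did. The numbers higher and lower at 39 °C moved from 18 and 83 to 8 and 37 at adjusted p under 0.01, and to 4 and 25 at an absolute log2 fold change of at least 1, by construction. They moved to 43 and 133 with any count, 67 and 161 with the length and GC trend removed, 181 and 301 with the ribosomal protein share as covariate, and 136 and 265 with only the 6 samples compared, and the higher genes moved to 38 with DESeq2; the cause was not tested. At least 2-fold changes numbered 1435 and 1398 at 37 °C, 1245 and 1242 at 39 °C and 2237 shared in direction. The 64 genes lower at 39 °C that rose on activation became 115 with the length and GC trend removed and 211 with the ribosomal protein share; the cause was not tested. Of the list calls, 1 of 5 for 39 °C against 37 °C held with an estimated correlation and 3 with fry, and 8 of 16 for 37 °C against naive held with an estimated correlation. With the ribosomal protein share as covariate 4 results at 37 °C against naive changed sign. These were Rbm3 (0.0074) and Notch2 (-0.019), then nearly without change, Notch1 (-0.55) and oxidative phosphorylation (adjusted p = 0.0261). The share was 10.5% to 14.8% in naive libraries and 7.98% to 9.06% at 37 °C, without overlap. Covariate and activation are thus confounded in this contrast, and the covariate may have taken up activation itself.

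Leaving out 1 library gave 7 to 89 genes higher and 30 to 202 lower at 39 °C, 25 to 147 in the split by activation, and 2 to 6 lists for 39 °C against 37 °C. The highest gene counts came without naive library 1. Spread between 2 libraries of a group, as chi-square per degree of freedom, was 44.1 and 25.0 in the naive pairs with library 1. It was 10.4 in the other naive pair and 2.14 to 10.1 in the activated pairs. The naive spread enters the shared estimate and can lower the number of calls between the temperatures. How much of the change in counts comes from it was not tested. The replicate numbers showed no sign of a pairing, as 0 of 9 libraries correlated best with their own number in both other groups. Libraries of the same number had r of -0.17 to 0.33 and others -0.34 to 0.36. So few libraries cannot exclude a pairing, since such a match would be rare without one too. With a block for the replicate number, counts were 16 and 81 between the temperatures, 4234 and 4285 at 37 °C and 4026 and 4039 at 39 °C, 89 of the 101 genes kept their call, Hspa1b, Atf3 and Dusp10 lost it, and Notch1 at 37 °C against naive gained one. Upper-quartile scaling gave 3340 and 5139 at 37 °C and 3092 and 4914 at 39 °C, and shifted the median of all genes by -0.14 and -0.13, so changes under it are relative to that shift. Under it Hspa1b and Tnfsf14 lost their call between the temperatures. No named gene reversed under the RLE, library size or upper-quartile scaling, and no list reversed under library size scaling, the only scaling of these that was run on the lists. The strand alternative could not be run, since each table has a single count column. Depth was tested by keeping 50% of the reads, or a share of 0.25, at random, 5 times each. Between the temperatures 10 to 14 genes were higher and 56 to 71 lower at 50%, against 18 and 83 with all reads. At the share of 0.25, 5 to 7 were higher and 39 to 48 lower. At 50% the standard errors of genes under 2 CPM grew by a median factor of 1.303, at 2 to 10 CPM of 1.27 and at 100 CPM or more of 1.052. The factor under 2 CPM covers only genes still tested, on average 1157 of 2565. Il4, under 1 CPM in each group, was no longer tested in any run. Depth thus limits the number of calls and the precision of genes under 10 CPM most. Of simulated changes of 0.32 on the log2 scale 3 of 48 were recovered, at the depth of these libraries alone.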

Other observations

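The tests of the hypoxia and ATF4 hypotheses were chosen after the result was seen. Several immediate early genes were higher in naive than in activated cells, chosen here after their values were seen. At 37 °C against naive Jun was at -2.58 ± 0.073, Fos at -2.06 ± 0.074, Dusp1, a phosphatase of MAP kinases, at -1.29 ± 0.089, Jund at -1.12 ± 0.13 and Klf6 at -0.97 ± 0.07, all called lower, while Egr1 was at 3.61 ± 0.073 and Nr4a1, induced by T cell receptor signals, at 3.85 ± 0.084. Jun and Fos were also lower at 39 °C against naive, at -2.94 ± 0.075 and -2.21 ± 0.074.

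P4ha2 (-1.73 ± 0.28), Plod1 (-1.14 ± 0.079) and P4ha1 (-1.02 ± 0.073), which encode collagen-modifying hydroxylases, were lower at 39 °C than at 37 °C, as was the lipid droplet gene Plin2 at -1.10 ± 0.14, all chosen after their values were seen. Of the related genes Plod2 (-0.42 ± 0.30), Plod3 (0.02 ± 0.14) and P3h1 (-0.068 ± 0.13) were not called. A lower hypoxia response at 39 °C might explain the hydroxylase genes, and would then lower other targets of hypoxia-inducible factor. The 22 other measured targets went both ways, 11 above 0 and 11 below (adjusted p = 0.325, camera). Their median was 0.017 and their mean -0.0041, with an SD of 0.19 across genes. These values argue against a fall of the 22 targets as large as that of the hydroxylase genes. A smaller shift, or 1 limited to few genes, cannot be told apart from other causes. Ddit3, Trib3, Pck2, Slc1a4, Slc7a11 and Atf3, higher at 39 °C, may belong to a broader ATF4 response. The 25 other measured ATF4 targets had a median of 0.071, with 14 above 0 and 11 below. Camera (limma) gave a shift upward with an unadjusted p under 0.05, adjusted p = 0.0513 over the 2 lists tested here and adjusted p = 0.153 with an estimated correlation, so the evidence is weak.

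Of the Y-linked genes, Eif2s3y was lower at 39 °C (-0.41 ± 0.073, adjusted p = 0.0231, edgeR), while Ddx3y (0.0026 ± 0.098), Kdm5d (-0.11 ± 0.10) and Uty (-0.045 ± 0.14) were not called, chosen after their values were seen. Xist was present in all 9 libraries, at 304 ± 66.6 CPM in naive, 287 ± 24.5 at 37 °C and 248 ± 38.1 at 39 °C. Ddx3y was at 46.2 ± 6.02, 98.4 ± 6.80 and 98.7 ± 8.92 CPM in the same groups. Single libraries had 211 to 379 CPM of Xist and 41 to 108 CPM of Ddx3y. Xist is a transcript of female cells, so these values argue against libraries of 1 mouse each. Whether the libraries came from separate pools stays open.

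Skeletal muscle genes were present in naive library 2 and near absent elsewhere, chosen after their values were seen. The 6 genes Acta1, Myl1, Myh4, Pvalb, Tnni2 and Ckm had 3002 counts there and 5 to 10 counts in each of the other libraries. The 12 stroma and endothelium markers had 415 counts there and 1 to 16 in the others. None of these 18 genes passed the count filter of the main fit.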
